A study of Mus musculus with 2 samples.

How the data were processed

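The data were 2 single-cell libraries of mouse lung, 1 labelled WT and 1 labelled KO, made with the 10x Genomics 3' v3 chemistry. Per the labels, lungs were treated with dispase for 1 hour and DNase for 30 minutes, and cells were sorted for VE-cadherin and against CD45. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 3.0.1 on mm10 per the submitters' processing notes. How many animals each library pooled is not given in the sources used here. Both matrices list 27998 genes, of which 27722 (99.0%) have their identifier in GENCODE M21, the annotation used for coordinates.

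Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which passed 2745 WT and 1326 KO barcodes. Scrublet, run per library through scanpy 1.11.5, called 37 WT (1.35%) and 12 KO (0.905%) doublets, which were removed. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes were chosen with the libraries as batches. Cells were clustered on 30 principal components with a graph of 20 neighbors and Leiden (leidenalg 0.10.2, python-igraph 0.11.9) at resolution 1. Within each named class of at least 50 cells per library, genes were listed that differed at least 1.5-fold with non-overlapping intervals. The 618 variable genes among these 2259 were left out, and clustering on the remaining 1382 gave the 15 clusters reported. An unnamed first-step cluster of 3 WT and 130 KO cells did not enter this listing, so genes that set it apart could stay among those used.

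Clusters were named from cell type markers fixed before the data were examined, of which 168 of 173 are in the files. A name needed 3 markers in at least 10% of cells and 2-fold above the median cluster, or for endothelial subclasses above the other endothelial clusters (10 CPM added to each), and among the cluster's top 10 genes at least 1 marker of its own and no more of another class. The scoring rule was revised after the first clusters had been seen: all endothelial markers were then counted as own markers at the first level, and a cluster with none of its own among the top 10 was left unnamed. Endothelial clusters 3 and 6 stayed unnamed, cluster 3 because markers of another class led it and cluster 6 because none of its own did. By ratio to the other endothelial clusters, the leading genes included Wfdc1, Sema3c, Aplnr and Hbb-bs in gCap-like cells, Fibin, Ednrb and Car4 in aCap-like cells, Bmx and Gja5 in arterial-like cells, and Slc6a2 and Vwf in venous-like cells. They included Esm1, Ivns1abp and Gja1 in cluster 3, and Igfbp3, Trp53i11 and Peg3 in cluster 6. The naming rule as first written, which blocked a name without own markers only at low depth, was run as an alternative. The thinning depth of 1500 UMIs, the definition of a KO-only cluster (at least 90% KO and 50 cells), the clustering without list genes, the removal of cells with at least 3 of 4 lymphatic markers, the shares outside the KO-only cluster, the comparisons within each sex and the count of UMIs held by the 5 highest cells were also chosen after the data had been seen.

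UMIs were summed per class and library and given as CPM of the class total, with exact Poisson intervals, and ratios with exact conditional binomial intervals, at 95%. A level of 0 was given a floor of 3 counts. Genes to name in gCap-like cells were the 12 highest and 12 lowest KO over WT ratios, at least 1.5-fold, among genes with a mean of at least 50 CPM and non-overlapping intervals. In the other endothelial classes they were the 4 highest and 4 lowest at 100 CPM. Mitochondrial, ribosomal protein, haemoglobin, predicted and sex-linked genes and markers of non-endothelial types were left out of these ranks, while Acvrl1 and 2 to 4 members of each list with the largest differences at 10 CPM were added. This rule was written before the data were examined. Arterial-like and venous-like cells were under 50 in KO and had no gene ranks.

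The 18 gene lists, of which 304 of 305 genes are in the files, were fixed before the data were examined: BMP-SMAD target genes, TGF-beta and BMP pathway components, Notch pathway, arterial identity, venous identity, angiogenesis and tip cell, shear stress response, endothelial junctions, extracellular matrix, mesenchymal transition, leukocyte adhesion and inflammation, interferon response, antigen presentation, cell cycle, dissociation and heat stress, hypoxia and glycolysis, fatty acid handling and oxidative phosphorylation. Each list's median log2 ratio over members with at least 10 CPM was placed among 10000 random lists of the same size matched on expression, as a description of these libraries. A list was called set apart beyond the outer 2.5% on either side, and a member higher or lower at 1.5-fold with non-overlapping intervals. For shares of cells with a UMI, each cell was thinned to 1500 UMIs, which left out 170 WT and 119 KO cells. Cells were typed by sex where they had UMIs of Xist or of Y-linked genes alone.

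The gene and list steps were tested on simulated Poisson counts drawn from the gCap-like sums, without variation between cells, animals or libraries. Clustering and naming were not simulated. The simulated results therefore speak for counting error alone. Of 3733 genes run, 101 of 101 changed 3-fold and 94 of 99 changed 2-fold passed the size rule, as did 7 of 3533 unchanged genes, and 95.3% of intervals held the true ratio. A list raised 2-fold was set apart, as were 0 of 13 lists sharing no member with it. Alternatives covered clustering genes and resolution, each library alone, cell filters, doublets, scaling, depth, class and list minimum. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. With 1 library per group, no p-value, standard error or count of differing genes is given as a finding.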

Results

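Single-cell RNA-seq was carried out on lung cells from C57BL/6J mice aged 10 to 12 weeks, with 1 library from wild-type animals (WT) and 1 from knockout animals (KO) in a model of hereditary hemorrhagic telangiectasia type 2, an inherited disease of malformed vessels. Cells had been sorted for VE-cadherin, an adhesion protein of endothelial junctions, and against CD45, a surface protein of leukocytes. The WT matrix held 3482 barcodes with 25667220 UMIs and the KO matrix 2196 barcodes with 17864581 UMIs. After filtering, 2708 WT and 1314 KO cells remained, with medians of 5423 and 8654 UMIs per cell. Each group was a single library, so no difference has a replicate check, none was tested, and the intervals given (95%, exact Poisson for levels, exact Clopper-Pearson for shares) cover counting error only. Sex-linked transcripts separated the animals: all 2376 WT cells that could be typed outside the leukocyte-like class had Xist alone, whereas 200 KO cells had Xist alone and 759 had Y-linked transcripts alone. Both kinds were seen in 3 WT and 20 KO cells.

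The labels name a knockout without its gene, and the disease type is known to come from ACVRL1, which encodes the endothelial BMP9 and BMP10 receptor ALK1. Acvrl1 (ENSMUSG00000000530, chromosome 15, 101128522 to 101145336, plus strand, GRCm38) differed by less than its counting error in general capillary (gCap-like) cells, at 1313 CPM (1269 to 1359) in WT and 1237 CPM (1166 to 1310) in KO, a ratio of 0.941 (0.880 to 1.01). In aerocyte (aCap-like) cells, the large alveolar capillary cells, it stood at 1908 and 1735 CPM. It stood at 1269 and 1302 CPM in endothelial cluster 3, 1053 and 927 CPM in arterial-like cells, and 828 and 612 CPM in venous-like cells. The lowest endothelial level in KO was in endothelial cluster 6, at 379.8 CPM (337 to 426). Over all endothelial-like cells the levels were 1456 and 1040.2 CPM, a ratio of 0.714 (0.685 to 0.745). With each cell thinned to 1500 UMIs, 86.4% of WT and 81.3% of KO gCap-like cells had an Acvrl1 UMI (94.6% and 91.1% unthinned, median depths 4163.5 and 5286.5 UMIs), with 42 WT and 24 KO cells left out as shallower. In KO cluster 6 cells it was 48.4% thinned, with 6 cells left out, and 81.1% unthinned. In alveolar type 2 (AT2-like) cells, which should lack the gene, it was 3.37% in WT and 0.555% in KO thinned and 22.4% and 5.25% unthinned, with 15 and 50 cells left out, at median depths of 17656 and 19632 UMIs. A 3' library may count transcripts whose deleted part lies elsewhere, so these levels do not decide whether the gene was deleted in a cell.

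The first comparison asked how the endothelial classes were represented in each library. Endothelial cluster 6 held 132 KO and 3 WT cells and made up 25.2% (21.5 to 29.1) of KO against 0.195% (0.0402 to 0.568) of WT endothelial-like cells. Aerocytes made up 25.8% (23.6 to 28.0) of WT and 13.5% (10.7 to 16.8) of KO endothelial-like cells. The shares were 39.8% and 36.3% for gCap-like cells and 27.1% and 18.9% for endothelial cluster 3. Arterial-like cells made up 3.70% and 3.44%, and venous-like cells 3.37% and 2.67%. A cluster almost wholly of 1 library may be a property of that library and not a cell type, and it lowers every other KO share. Outside it, aCap-like cells made up 25.8% (23.6 to 28.1) of WT and 18.1% (14.4 to 22.3) of KO cells, and gCap-like cells 39.9% (37.5 to 42.4) and 48.5% (43.4 to 53.5), so that the order of the gCap-like shares turned with the denominator. Of all cells kept, 56.9% (55.0 to 58.8) of WT and 39.9% (37.2 to 42.6) of KO were endothelial-like, while AT2-like cells made up 30.2% and 45.0% despite the VE-cadherin sort. These shares may in part reflect the sort and the filters, which was not tested for them. Of all barcodes, 15.1% in WT and 30.5% in KO exceeded the mitochondrial limit. Median depth was 4209 UMIs in WT and 5064 in KO endothelial-like cells.

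**Figure D1:**
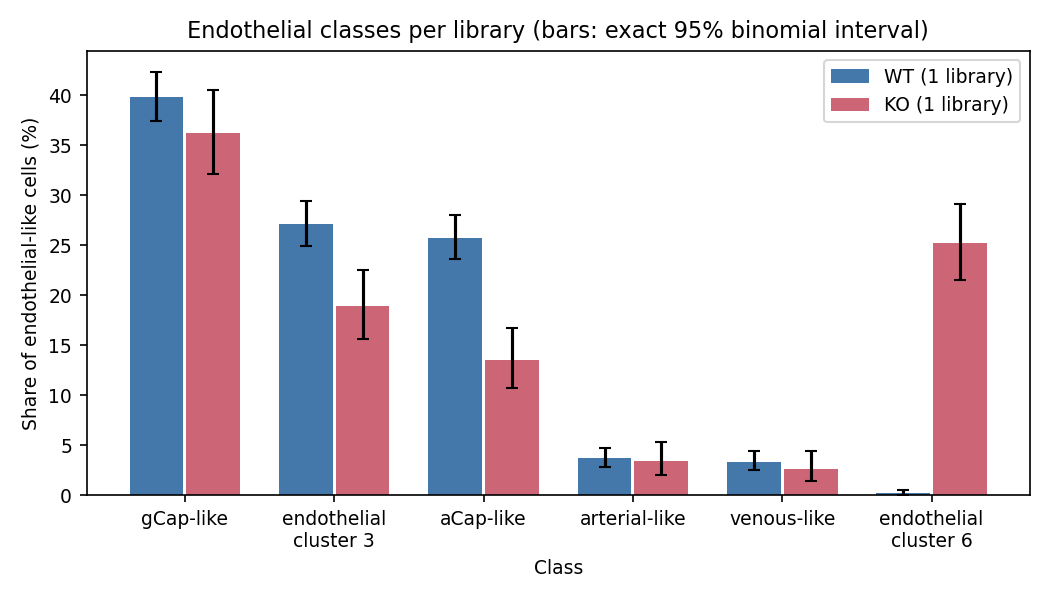
Share of endothelial-like cells (percent, vertical axis) in each endothelial class (horizontal axis) for the WT and KO libraries, 1 library each, with exact 95% binomial intervals as error bars. Endothelial cluster 6 reaches 25.2% in KO against 0.195% in WT, and the aCap-like share is 25.8% in WT and 13.5% in KO.

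Pooled over both sexes, the BMP-SMAD target list lay lower, and the angiogenesis and tip cell and extracellular matrix lists higher, in KO cells of the KO-only cluster. To keep these genes from directly defining the cells, all genes of the fixed lists were left out and the cells clustered again, a step chosen after cluster 6 had been seen. The 1341 genes still used can vary together with list genes, so the list contrasts are not independent of the clustering. A KO-only cluster of 111 KO and 0 WT cells returned, of which 110 were shared with the 132 KO cells of cluster 6. Against the 381 other KO endothelial-like cells, Id1, an inhibitor of differentiation induced by BMP receptors, stood at 31.4 CPM (19.2 to 48.5) against 819.6 CPM (780.4 to 860.2). Id3, its relative, stood at 48.7 CPM (33.1 to 69.1) against 968 CPM (925 to 1012), and the inhibitory SMADs Smad6 and Smad7 at 115 against 549 and 88.0 against 603 CPM. The BMP-SMAD target list had a median log2 ratio of -2.52, with 11 of 12 measured members lower and 0 higher. Apln, a tip cell peptide, stood at 1381 CPM (1291 to 1475) against 180.2 CPM (162 to 199.8), and Angpt2, which destabilizes vessels, at 320.4 against 26.5 CPM. Col4a1, a basement membrane collagen, stood at 7153 against 2109 CPM, and Smad1, which carries the BMP signal, at 734 against 108 CPM. The angiogenesis and tip cell list (13 of 22 members higher, 5 lower) had a median of 1.25, and the extracellular matrix list (11 of 20 higher, 4 lower) one of 0.80. These lists share Col4a1, Col4a2, Lama4 and Nid2.

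The same cells differed in further lists. The arterial identity list, with Cxcl12 at 48.7 against 712 CPM, had a median log2 ratio of -1.23 (3 higher and 11 lower of 17) and shares Gja4, Gja5 and Hey1 with the BMP-SMAD list. The venous identity list, with Aplnr at 20.4 against 197 CPM, had one of -1.28 (0 higher and 6 lower of 10). Among the fixed markers, Aplnr also marks gCap-like cells, and Apln of the tip cell list also marks aCap-like cells. Their levels may therefore reflect the capillary classes among the cells outside the cluster, which was not tested. The hypoxia and glycolysis and mesenchymal transition lists lay higher, at 0.46 (7 higher and 1 lower of 16) and 0.42 (3 higher and 3 lower of 13), and the interferon response list lower, at -0.37 (2 higher and 1 lower of 21). Over WT endothelial-like cells the BMP-SMAD, tip cell and matrix medians were -2.52, 1.02 and 1.17, and those of arterial identity, venous identity and hypoxia and glycolysis -1.10, -1.85 and 0.61. Mesenchymal transition (0.21) and interferon response (-0.27) were not set apart over WT, and over other KO cells the counting interval of the mesenchymal median reached from -0.15 to 0.52. Antigen presentation (-1.01) and dissociation and heat stress (-0.37) lay lower over WT alone. The sexes were spread unevenly: 76.6% of Xist-only and 17.5% of Y-only KO endothelial-like cells lay in cluster 6. Among Y-only cells (44 in the cluster, 222 outside) the BMP-SMAD median was -2.26 and the matrix median 0.90. Among Xist-only cells (52 and 25) they were 0.19 and -0.68, so the pooled contrast did not hold there, while the tip cell median was 0.57. Acvrl1 stood at 471 CPM inside and 1352 CPM outside the cluster in Y-only cells, and at 369 and 597 CPM in Xist-only cells. Id1 stood at 34.7 CPM inside and 79.6 CPM outside the cluster in Xist-only cells, and at 37.2 and 829 CPM in Y-only cells. The members named here were chosen after their values had been seen, and the 7 KO cells of cluster 6 with lymphatic markers did not enter the cluster's levels. The cells outside were all other KO endothelial-like cells of the clustering without list genes. They included 7 lymphatic-like KO cells from cluster 6 and could include other cluster 6 cells that did not return. Since 59 of 77 Xist-only KO endothelial-like cells lay in cluster 6, some of the 25 Xist-only cells outside may be such cells. No typed KO gCap-like cell of the reported classes had Xist alone, so the cells outside also differed in class between the sexes.

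**Figure D2:**
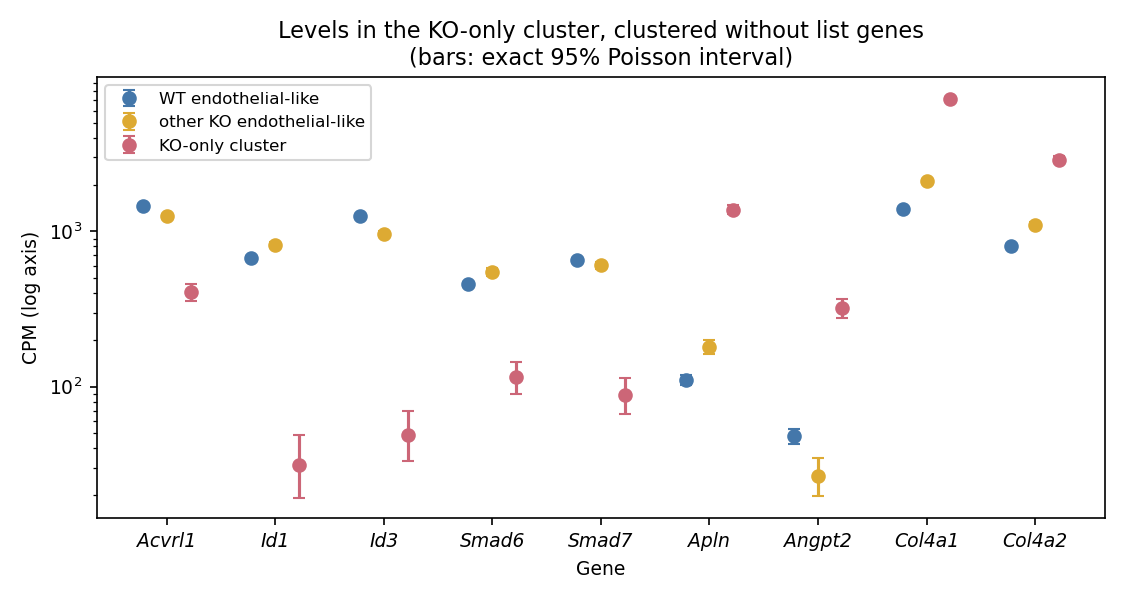
Levels of 9 genes (CPM, logarithmic vertical axis) in WT endothelial-like cells, other KO endothelial-like cells and the KO-only cluster, clustered without the genes of the fixed lists, with exact 95% Poisson intervals as error bars. Id1 lies at 31.4 CPM in the cluster against 819.6 CPM in other KO cells and 670.1 CPM in WT cells, and Apln at 1381 against 180.2 and 110.1 CPM.

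The second comparison set KO against WT within gCap-like cells (614 WT and 190 KO cells). Genes lower in the KO library included immediate early and heat shock genes. Egr1, an immediate early transcription factor, stood at 179 CPM (163 to 196) in WT and 18.2 CPM (10.6 to 29.2) in KO, and Fos, a subunit of the AP-1 factor, at 88.3 and 12.9 CPM. Hspa1a and Hspa1b, the inducible HSP70 chaperones, stood at 142 and 18.2 CPM and 92.6 and 15 CPM, and Hspb1, a small heat shock protein, at 124 and 32.1 CPM. Ifi204 (ENSMUSG00000073489), of an interferon-inducible family of near-identical genes on chromosome 1 (173747293 to 173766943), had 163 CPM in WT and 0 UMIs in KO, at least 50.6-fold lower against a floor of 3 counts in the KO total. H2-Q7, a class I histocompatibility gene, stood at 244 CPM (225 to 264) in WT and 75.0 CPM (58.5 to 94.8) in KO. Reads of the Ifi200 and H2-Q families and of the Hspa1a and Hspa1b pair can be shared between near-identical copies, so their levels are uncertain. The other lower genes were Fmo2 (283 and 81.4 CPM), Gsn (78.9 and 22.5 CPM) and Lamtor3 (87.5 and 21.4 CPM). Scd1 (205 and 66.4 CPM) and Lyz1 (221 and 72.9 CPM) were also lower, and both are abundant in AT2-like cells, at 3127 and 7716 CPM in WT. Sftpc, a surfactant gene of AT2 cells, stood at 2919 CPM in WT and 1562 CPM in KO gCap-like cells. It may be present there as free RNA, which was not tested. Egr1, Fos, Hspa1a, Hspa1b, Lamtor3, Scd1 and Lyz1 were not particular to this class. They also lay at least 1.5-fold lower in aCap-like, AT2-like, fibroblast-like and smooth muscle-like cells of the KO library. Ifi204 and H2-Q7 were not particular to gCap-like cells either. In endothelial cluster 3 Ifi204 had 375 UMIs in WT and 0 in KO, and H2-Q7 stood at 164 and 51.5 CPM. In AT2-like cells, where both were low, Ifi204 stood at 2.93 and 0.55 CPM and H2-Q7 at 7.28 and 1.65 CPM. The 12 lower genes ranked by size stayed lower in the alternatives that gave values, but the log2 ratio of Hspb1 (-1.95) was -0.83 with cells thinned to 1500 UMIs, and those of Gsn (-1.81) and Lamtor3 (-2.03) were -1.0 and -1.28 under the first naming rule, an alternative chosen after seeing the data. Over all endothelial-like cells Egr1 (-3.29), Fos (-2.78), Hspa1a (-2.96), Hspa1b (-2.63), Fmo2 (-1.80) and Gsn were at -2.06, -2.09, -1.69, -1.65, -1.10 and -0.96. The filter of at least 200 genes and at most 20% mitochondrial UMIs gave -2.19 for Hspa1a and -1.83 for Hspa1b. Larger ratios of Egr1, Hspa1a and Lamtor3 in thinned cells, and of Hspa1a under the first naming rule, rested on 2 or 3 KO UMIs and are not given.

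Genes higher in KO gCap-like cells were led by Rnf121 and Tmem252. Rnf121 (ENSMUSG00000070426, chromosome 7, 102019137 to 102065469), a ring finger ubiquitin ligase, stood at 16.9 CPM (12.2 to 22.7) in WT and 94.3 CPM (75.6 to 116) in KO, and Tmem252, a membrane protein, at 55.3 CPM (46.6 to 65.3) in WT and 304 CPM (269.9 to 342) in KO. Ctgf, a matricellular protein, stood at 35.7 and 120.0 CPM, Adamts9, a secreted metalloprotease, at 68.3 and 183 CPM, and Plat, the tissue plasminogen activator, at 49.5 and 121 CPM. Ctgf was also at least 1.5-fold higher in aCap-like, AT2-like, fibroblast-like and smooth muscle-like cells of the KO library. The transcription factor genes Jdp2, Hlx and Pknox2 stood at 54.2 and 146 CPM, 63.2 and 146 CPM and 30.6 and 80.4 CPM. Ifi44, an interferon-induced gene, stood at 31.8 and 77.2 CPM, and Hebp1, Tubb2b and Fkbp14 had ratios of 2.32, 2.29 and 2.21. Few cells carried much of some signals: the 5 highest KO cells held 31.2% of Ctgf and 33.3% of Ifi44 UMIs. Under the first naming rule the log2 ratios of Ctgf (1.75), Hebp1 (1.22) and Hlx (1.21) were 0.54, 0.49 and 0.57, all under 1.5-fold, and that of Rnf121 (2.48) was 1.26. Ctgf was at 1.05 with at least 200 genes and at most 20% mitochondrial UMIs, 1.13 with at least 1000 genes and at most 5%, 0.98 thinned, 1.09 with cluster 3 joined and 2.92 over all endothelial-like cells, where Hlx was at 0.42, also under 1.5-fold, and Rnf121 at 1.49. Fkbp14 (1.14) was at 1.78 thinned. The WT and KO counting intervals of all genes named here other than Acvrl1 were apart as reported. None of the 98 typed KO gCap-like cells had Xist alone, which by the floor of 3 counts allows a share of up to 3.06%, and all 537 typed WT ones had, so this comparison also set females against males.

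Of the 18 fixed gene lists, antigen presentation and dissociation and heat stress lay below their matched random lists in gCap-like cells. Antigen presentation had a median log2 ratio of -0.81, at percentile 0, with 7 of 8 members lower. H2-K1 and H2-D1, the classical class I heavy chains, stood at 2289 and 1256 CPM and 6632 and 3924 CPM, and B2m, their light chain, at 2278 and 1432 CPM. Cd74, the class II invariant chain, stood at 79.3 and 10.7 CPM, beside 2905 and 1488 CPM in AT2-like cells, whose free RNA can carry it. Dissociation and heat stress had a median of -0.46, at percentile 0, with 6 of 18 members lower and 0 higher, among them Junb at 227 and 92.2 CPM. The BMP-SMAD target list was not set apart, with a median of -0.03, Smad6 and Stc1 higher (346 and 564 CPM and 22.8 and 41.8 CPM) and Id2 lower (153 and 73.9 CPM) among 11 members. The TGF-beta and BMP pathway components list had a median of -0.09, with Inhbb higher and Tgfbr3 and Smad5 lower of 19 members. With no minimum beyond 3 UMIs the BMP-SMAD list was set apart higher, at 0.35, and with cluster 3 joined the pathway components list was set apart lower, at -0.15. The extracellular matrix median was 0.08 (2 higher and 1 lower of 18), with Sparc, a collagen-binding protein, at 1059 and 2044 CPM, Fn1, fibronectin, at 13.0 and 49.3 CPM and Sparcl1 at 497 and 227 CPM. Sparc, too, was at least 1.5-fold higher in aCap-like, AT2-like, fibroblast-like and smooth muscle-like cells of the KO library. In the shear stress list, at 0.07 (1 higher and 0 lower of 13), Klf4, a flow-induced factor, stood at 628 and 1091 CPM.

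The remaining lists were also not set apart in gCap-like cells. Their medians, with members past the size rule, were 0.13 (1 higher and 0 lower of 13) for Notch pathway, -0.10 (0 higher and 0 lower of 14) for arterial identity, -0.16 (0 higher and 1 lower of 7) for venous identity, 0.02 (1 higher and 2 lower of 19) for angiogenesis and tip cell, and 0.13 (1 higher and 0 lower of 14) for endothelial junctions. They were -0.02 (1 higher and 0 lower of 10) for mesenchymal transition, -0.11 (0 higher and 1 lower of 9) for leukocyte adhesion and inflammation, 0.04 (0 higher and 3 lower of 21) for interferon response and 0.18 (0 higher and 0 lower of 4) for cell cycle. They were -0.12 (0 higher and 0 lower of 13) for hypoxia and glycolysis, 0.09 (0 higher and 1 lower of 12) for fatty acid handling and 0.10 (0 higher and 0 lower of 20) for oxidative phosphorylation. Single members differed, such as Hes1, a Notch target, at 252 and 415 CPM, and Iigp1, an interferon-induced GTPase, at 253 and 140.4 CPM. The gCap-like name moved to other cells under several clustering settings, and 2 to 7 lists were set apart over 11 alternative settings, with extracellular matrix higher in 5 of them (medians 0.18 to 0.69) and venous identity lower in 4 (-0.26 to -0.67).

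**Figure D3:**
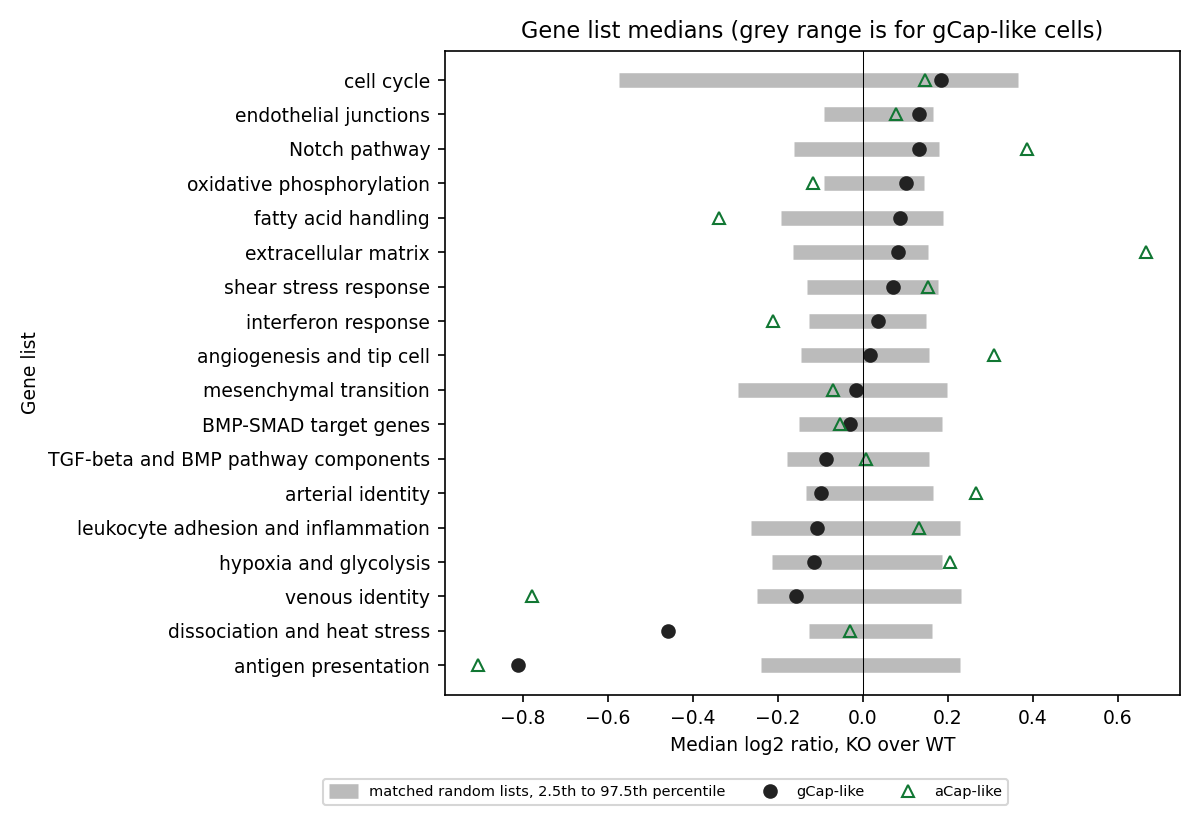
Median log2 ratio of KO over WT (horizontal axis) for each of the 18 gene lists (vertical axis) in gCap-like cells (filled circles) and aCap-like cells (open triangles), 1 library per group. Grey bars span the central 95% of 10000 matched random lists for gCap-like cells, and antigen presentation (-0.81) and dissociation and heat stress (-0.46) lie below theirs.

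In aCap-like cells (397 WT and 71 KO cells), the extracellular matrix list lay higher and the antigen presentation list lower in the KO library. The extracellular matrix list had a median log2 ratio of 0.67, with 6 of 16 members higher, among them Lamc1, a laminin chain, at 199 and 474 CPM and Col4a1 at 1865 and 3599 CPM. The angiogenesis and tip cell list, with Apln at 325 and 663 CPM, had a median of 0.31 (4 higher and 0 lower of 16), the Notch pathway list one of 0.39 (1 higher and 0 lower of 12) and the arterial identity list one of 0.27 (2 higher and 0 lower of 12). The counting interval of the arterial median reached from -0.0044 to 0.49. Antigen presentation lay lower at -0.91, with 4 of 6 members lower, as did fatty acid handling at -0.34 (1 higher and 0 lower of 12) and venous identity at -0.78 (0 higher and 1 lower of 4). Dissociation and heat stress was not set apart, at -0.03 (1 higher and 3 lower of 17), and the difference from gCap-like cells was not tested. Of its members, Fos and Hspa1a had log2 ratios of -1.84 and -1.83. Lyve1, a hyaluronan receptor, stood at 171 CPM (154 to 189) in WT and 970.3 CPM (879.7 to 1068) in KO, with 49.8% of its KO UMIs in 5 cells. Hebp1 and Klf6 were also higher, with ratios of 2.60 (1.95 to 3.45) and 2.44 (2.02 to 2.94). Hspb1 and H2-Q4 were lower, with ratios of 0.441 (0.356 to 0.540) and 0.442 (0.309 to 0.617). Lyz1 and Cxcl15 were lower at 0.225 (0.130 to 0.365) and 0.343 (0.238 to 0.481), and both are AT2 transcripts, beside Sftpc at 2374 and 1127 CPM. Of the typed KO cells, 8 had Xist alone and 47 Y-linked transcripts alone.

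In endothelial cluster 3 (418 WT and 99 KO cells, medians of 3091.5 and 3113 UMIs), the antigen presentation and stress lists lay lower and the extracellular matrix list higher in the KO library. Ifi204 had 275 CPM in WT and 0 UMIs in KO, at least 30.3-fold lower. Junb, an AP-1 subunit, Hspb1 and H2-Q7 were lower, with ratios of 0.204 (0.110 to 0.347), 0.299 (0.180 to 0.471) and 0.313 (0.179 to 0.513). Tmem252, Tmem2, a cell surface hyaluronidase, and Pdlim5 were higher, with ratios of 5.74 (3.78 to 8.80), 2.80 (2.49 to 3.14) and 2.65 (1.98 to 3.54). Peg3, an imprinted gene, stood at 79.9 and 230.1 CPM, and 5 cells held 57.9% of its KO UMIs and 42.1% of those of Tmem252. Antigen presentation (-1.22, 0 higher and 5 lower of 8), dissociation and heat stress (-0.42, 0 higher and 7 lower of 18), hypoxia and glycolysis (-0.44, 0 higher and 1 lower of 14) and oxidative phosphorylation (-0.45, 0 higher and 3 lower of 20) lay lower. Extracellular matrix (0.33, 4 higher and 1 lower of 17), mesenchymal transition (0.40, 1 higher and 0 lower of 10) and arterial identity (0.26, 1 higher and 0 lower of 15) lay higher. The counting interval of the mesenchymal median reached from -0.025 to 0.65. Of the typed KO cells, 9 had Xist alone and 51 Y-linked transcripts alone.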

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

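The tests of the pseudogene share and of B2m were chosen only after the cluster had been seen. Ribosomal protein pseudogenes stood out in the leukocyte-like cells, a class used in no comparison, in both libraries. They took 1.60% (1.55 to 1.65) of UMIs in 82 WT and 1.73% (1.62 to 1.85) in 25 KO leukocyte-like cells, against 0.0281% and 0.0287% in all other cells.

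All 107 leukocyte-like cells, and 1 of 3915 other cells, had more than 0.3% of their UMIs on these pseudogenes. Mouse leukocytes that escaped the CD45 sort would carry B2m at a leukocyte level. Its ratio to the 10 neutrophil-like cells was 0.203 (0.146 to 0.286), which argues against leukocytes with B2m at the level of those cells. Leukocyte types with less B2m had no reference here, and Tyrobp, a fixed leukocyte marker, was among the cluster's top 10 genes. Reads from another organism, aligned to the closest mouse copies, cannot be told apart from other sources, because the pseudogene share, at least 56.9 times that of other cells in both libraries, is itself what singled these cells out. Median mitochondrial content was also low, at 0.797% and 0.448% against 4.29% and 4.68%. It was 1.01% in the neutrophil-like cells of both libraries together, so a low value does not set these cells apart from mouse leukocytes. Beyond mouse leukocytes, no biological explanation was tested.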

How the results depend on the processing

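The tests with the naming rule as first written, gCap-like cells joined with endothelial cluster 3, all endothelial-like cells without the KO-only cluster, and clustering without list genes were chosen only after seeing the data. The aCap-like share stayed lower in KO in the 9 alternatives run, by -10.4 to -17.8 percentage points (-12.2 as reported), the last under the first naming rule. KO-only clusters held 22.6% to 33.6% of KO endothelial-like cells in 8 alternatives, against 25.2% as reported, with 33.6% under the first naming rule. The gCap-like difference (-3.58 points) was -11.6 at resolution 0.5, 25.0 with each library clustered alone, -11.5 with at least 200 genes and at most 20% mitochondrial UMIs, -11.5 with at least 1000 genes and at most 5%, and -14.3 under the first naming rule. The class held 23.5% to 99.8% of the reported gCap-like cells in the settings that gave one, so its share depends on the setting. The arterial-like difference (-0.264) was -9.97 on all variable genes and -18.6 with each library alone, where the venous-like one (-0.703) was 1.88. With Scrublet calls kept no cluster was gCap-like, and at resolution 0.5 none was arterial-like, so these gave no values. The Acvrl1 log2 ratio (-0.09) was -0.20 with cells thinned to 1500 UMIs and -0.49 over all endothelial-like cells, but -0.16 without the KO-only cluster. The number of lists set apart (2) was 4 with at least 200 genes and at most 20%, 5 under the first naming rule, 7 in all endothelial-like cells, 5 without the KO-only cluster, 4 with cluster 3 joined, 4 with no minimum beyond 3 UMIs and 4 at 50 CPM. Antigen presentation and dissociation and heat stress were among them, both lower, in each of the 11 alternatives that gave calls. BMP-SMAD targets were set apart higher with no minimum beyond 3 UMIs, and pathway components lower and endothelial junctions higher with cluster 3 joined. Extracellular matrix was higher with at least 200 genes and at most 20%, under the first naming rule, in all endothelial-like cells with and without the KO-only cluster, and at 50 CPM. Venous identity was lower with cells thinned, in all endothelial-like cells, with no minimum and at 50 CPM. The Notch pathway was higher with at least 200 genes and at most 20% and without the KO-only cluster. Under the first naming rule interferon response was higher and oxidative phosphorylation lower, hypoxia and glycolysis was lower on all variable genes and higher in all endothelial-like cells, where tip cell and shear stress lists were also higher, and arterial identity was higher without the KO-only cluster. The venous identity median turned to 0.14 with at least 200 genes and at most 20%, 0.031 with at least 1000 genes and at most 5%, and 0.036 with cluster 3 joined. The oxidative phosphorylation median turned to -0.00048 with at least 200 genes and at most 20% and -0.16 under the first naming rule. Except where stated, the cause was not tested. Of the other list medians 181 kept within counting error and 29 moved, and of named gene ratios 180 and 35, with 0 reversed. Ctgf and Hebp1 under the first naming rule, and Hlx there and in all endothelial-like cells, were under 1.5-fold. Median-of-ratios scaling shifted all genes by 0.02 (log2). The 190 KO gCap-like and 71 KO aCap-like cells limit what could be seen in low genes.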

Other observations

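The tests of stress, of a single animal and of Acvrl1 in the KO-only cluster, and the comparisons in AT2-like, fibroblast-like and smooth muscle-like cells, were chosen only after the result was seen. AT2-like cells, which the sort was meant to remove, also differed between the libraries. H2-Aa and H2-Ab1, class II histocompatibility chains, stood at 765 and 293 CPM in WT and KO and at 509 and 197 CPM, and B2m at 339.7 and 155 CPM. The antigen presentation list had a median log2 ratio of -1.05, with 8 of 8 members lower, and the interferon response list one of -1.27, with 9 of 10 lower. Sfn, an epithelial 14-3-3 protein, was higher at 69.6 and 198 CPM. Spp1, Scgb1a1, a marker of airway secretory cells, and Mgp stood at 0.928 and 226 CPM, 378 and 4725 CPM and 24.1 and 237 CPM, with 99.0%, 79.9% and 91.1% of their KO UMIs in 1 cell and 99.2%, 92.4% and 92.9% in 5 cells, counted per gene. Without the highest cell, Spp1 and Mgp fell to 2.21 and 21.2 CPM in KO. Scgb1a1 still stood at 956 CPM without it, and 494 of 591 KO cells had a UMI of it.

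In smooth muscle-like cells (92 WT and 61 KO) the dissociation and heat stress list lay lower, at a median of -1.37 with 14 of 19 members lower, including Hspa1a at 696 and 142 CPM. In fibroblast-like cells (131 and 85) it lay lower at -0.75, with 11 of 18 members lower, and in AT2-like cells at -0.12 (1 higher and 5 lower of 18). Transcripts of other cell types differed with these lists. In fibroblast-like cells the AT2 transcripts Sftpc and Sftpd stood at 12788 and 838 CPM and 462 and 30.4 CPM in WT and KO, with 88.8% and 84.9% of their WT UMIs in 5 cells, and the endothelial junctions list lay lower, at -0.80 (0 higher and 4 lower of 13). In smooth muscle-like cells Sftpc stood at 1904 and 797 CPM, Dcn, a fibroblast gene, at 729 and 147 CPM with 88.6% of its WT UMIs in 5 cells, and the endothelial junctions list lay lower, at -0.78 (0 higher and 5 lower of 14). The extracellular matrix list lay higher in smooth muscle-like cells, at 0.41 (8 higher and 2 lower of 22), and in AT2-like cells, at 0.46 (4 higher and 0 lower of 12), and was not set apart in fibroblast-like cells, at 0.13 (7 higher and 4 lower of 24). Across 3247 genes, the log2 ratios of gCap-like and aCap-like cells correlated with Pearson r 0.41 and Spearman rho 0.31, where genes are not independent replicates. Of the other pairs computed, gCap-like cells with cluster 3 gave r 0.48 and rho 0.27, and with AT2-like cells r 0.15 and rho 0.33.

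The KO-only endothelial cluster was weighed against stress, a single animal and sex. Its dissociation and heat stress list lay at percentile 64.8 of matched lists over the other KO cells (1 of 18 members higher, 5 lower), with 1.12 times their mitochondrial content, and 55.7% of its typed cells had Xist alone, which argues against stressed cells and a single animal. Within Y-only cells sex does not differ, and the BMP-SMAD median there was -2.26 with 11 of 12 members lower. Sex is therefore not the whole cause for these cells. The cluster was formed from expression, however, so this contrast is not independent of the clustering. Among Xist-only cells the median was 0.19, and Id1 was low inside and outside the cluster. Loss of Acvrl1 signalling in part of the KO cells is a candidate explanation, with Acvrl1 at 0.324 times the other KO cells and the BMP targets low. The Xist-only values do not decide whether such loss reached cells outside the cluster, since only 25 such cells lay there. Among Xist-only cells the ratio of the cluster to those outside was 0.437 (0.175 to 1.08) for Id1 and 0.619 (0.466 to 0.824) for Acvrl1. Loss of Acvrl1 signalling remains a hypothesis, since lower Acvrl1 may also follow from another cell state, and animals, library and genotype are confounded.

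The antigen presentation list lay lower in KO in gCap-like, aCap-like, cluster 3 and AT2-like cells, and also in fibroblast-like cells, at -0.93 (0 higher and 4 lower of 6), and smooth muscle-like cells, at -0.69 (0 higher and 3 lower of 5), where the AT2 transcript Sftpc was lower too, at 0.0655 and 0.418 times its WT level. In AT2-like cells sex as the whole cause of the lower list median is excluded. There 83 Xist-only KO cells had a list median of -1.40 (-1.61 to -1.23) over WT with 7 members, and 396 Y-only cells one of -1.03 with 8. Single members differed, with H2-D1 at 0.814 times WT (0.775 to 0.855) in Xist-only and 0.562 times (0.545 to 0.579) in Y-only cells. H2-K1 stood at 0.486 and 0.524 times WT, and B2m at 0.378 and 0.460 times. A strain or donor variant in 1 chromosome region cannot be told apart: of 17 genes that differed alike in 5 classes, the fullest window of 20 Mb held 2, the median of 2000 random sets. The bound written beforehand counted such a tie against a variant, but with 17 genes a tie lies within the spread of random sets, which reached 3 at their upper end, and excludes nothing, a reading made after the value was seen. H2 genes were left out of the 17, and Ifi204, with 0 UMIs in KO gCap-like cells, was not among them. More than 1 window held 2 genes, among them that of Hspa1b and Hspa1a (from 34956436 and 34969190). This pair lies on chromosome 17 between H2-Aa (34282744) and H2-Q7 (35439155), so the window count does not speak for or against that region. A difference between the animals, their housing or the libraries may remain, as may an effect of the knockout, which was not tested.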
